A study of Mus musculus with 6 samples.

How the data were processed

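Ovarian RNA from 6 samples was analysed, 3 of high and 3 of low litter size, grouped by the litter size in the labels. Replicate numbers came from the titles. Values are estimated counts per gene as deposited. The submitters' processing notes name Trim Galore, kallisto, DESeq2 and the GRCm38 build, without versions. The values are whole numbers, and they were taken as rounded kallisto estimates, which is not stated. The release of the gene annotation is not given in the sources used here. kallisto shares reads between similar transcripts, so near-identical paralogs and pseudogenes are uncertain. The table held 36727 genes, of which 21888 were protein-coding and 13517 pseudogenes. Symbols came from a separate list of gene names for 35869 genes, and 858 had none. Coordinates and gene types are from the GENCODE M21 annotation, on GRCm38, which held 35948 of the genes.

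Total estimated counts ran from 17620903 to 24758222, a 1.41-fold range. Counting intervals cover counting error only. Spearman correlations between libraries were 0.939 to 0.952 within and 0.936 to 0.949 between groups. The first principal component of the 1000 most variable genes held 41.6% of variance and the second 25.2%.

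Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16455. Counts were TMM-normalized and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, high minus low, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.219, a biological coefficient of variation of 46.8%. No covariate was fitted. DESeq2 1.42.0 was an alternative, and its 822 undefined adjusted p-values were left undefined. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists of at least 5 tested members. Camera with an estimated correlation, fry and camera on ranks were alternatives. Plots and summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

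The 29 lists, the 15 key genes, the tests and a set of other settings were fixed before the data were examined. Of the listed genes, Ahsp was not matched, and alternative names of ATP synthase genes were merged. The named genes were, in each direction, up to 12 that passed, with groups that did not overlap, at least 1 CPM in the higher group and no predicted model name. Where under 5 qualified, the 5 of smallest p under the other criteria were taken, as values that do not pass, and 6 predicted models were skipped. The key genes were always named. Of each list up to 4 members of smallest p were eligible, and the text gives the 2 of smallest p, except for results that are not reported here. That narrowing to 2 was set after the values were seen.

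The tests were run on simulated counts drawn from the means and library sizes of these samples, with 200 genes changed. For the comparison of high with low litter size, edgeR recovered 0% of genes changed 2-fold, 10.5% of those changed 4-fold and 87% of those changed 16-fold, with 0, 1 and 7 false calls. DESeq2 recovered 6, 71 and 98%, with 31, 80 and 65 false calls. With no gene changed, edgeR made 0 and DESeq2 43 false calls.

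The settings fixed in advance were DESeq2, RLE, upper-quartile and library-size scaling, no filter, a minimum of 1 CPM in 3 libraries, limma voom, the edgeR likelihood ratio test, robust dispersion, adjusted p under 0.1, a minimum absolute log2 fold change of 1, and each library left out. Covariates of marker level, the joint removal of 3 libraries and 7 further gene lists were added after the data were seen. The 7 lists are Mullerian tract Hox genes, oestrogen-induced uterine genes, general epithelial genes, progesterone-induced uterine genes, stratified epithelium genes, plasma cell genes and oocyte-restricted genes.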

Results

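RNA was sequenced from ovarian tissue, which the labels describe as staged by estrous phase, of female F4 inbred Swiss albino mice. The females were 135 to 140 days old, and the 6 libraries came from 3 samples of the high litter size group (replicates 1, 3 and 4) and 3 of the low litter size group (replicates 1, 2 and 5). Litter size, the number of young per birth, is the only difference the labels give between the groups. Libraries were made from polyadenylated RNA. Total estimated counts were 18038084, 19123306 and 18146486 in high litter size replicates 1, 3 and 4, and 17620903, 19202937 and 24758222 in low litter size replicates 1, 2 and 5. Levels are given as CPM, counts scaled to the TMM-normalized library total. Before TMM normalization, 1 count corresponded to 0.0568 CPM in the smallest library. The labels do not say whether the samples came from separate animals, so the p-values measure the spread between these samples, which may be technical.

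The comparison of high with low litter size addressed which ovarian genes are related to fitness, in the terms of the study's title. 1 of 16455 tested genes passed, the immunoglobulin heavy chain variable segment Ighv1-9, which was lower in the high litter size group (log2 fold change -7.06, SE 0.46, edgeR quasi-likelihood adjusted p = 0.031, lower in 3 of 3 libraries). Its level was 0.0922 ± 0.0376 CPM in the high group and 13.0 ± 1.73 CPM in the low group (SD, n = 3). Star, a gene of steroid synthesis, ranged from 15.8 to 2418 CPM within the high group and from 16.8 to 932 CPM within the low group, and Inha, a granulosa cell gene, from 1.64 to 199 CPM and from 1.23 to 182 CPM. With a preset correlation in camera, 8 of 29 gene lists passed, among them fat and endothelial markers, higher in the high group, and smooth muscle markers, lower. With an estimated correlation 0 lists passed (adjusted p = 0.953 for each of the 8), and fry also gave 0.

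Ighv1-9 (ENSMUSG00000094694) lies on chromosome 12 from 114583569 to 114584002 (GRCm38, GENCODE M21 annotation, variable segment gene). Its counts were 1, 2 and 2 in the high libraries and 199, 237 and 382 in the low libraries. The ratio of summed counts, low over high and scaled by the TMM-normalized library sizes, was 147, with a 95% counting interval of 62.75 to 454. Variable segments are close paralogs of each other, so the share of reads given to each is uncertain. The call was lost when any 1 library was left out (adjusted p from 0.0839 without low replicate 5 to 0.381 without low replicate 2), while its log2 fold change stayed between -7.31 and -6.79. DESeq2 called 1026 genes on the same counts, 354 higher and 672 lower, Ighv1-9 among them. At an unadjusted p under 0.05, edgeR gave 2365 genes, 1079 higher and 1286 lower, where 823 would be expected with no gene changed. Other splits of the libraries into 3 and 3 gave 267 to 1244 such genes. The 3 high libraries lay entirely above or below the 3 low libraries for 19.53% of genes, against 10% by chance.

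**Figure D1:**
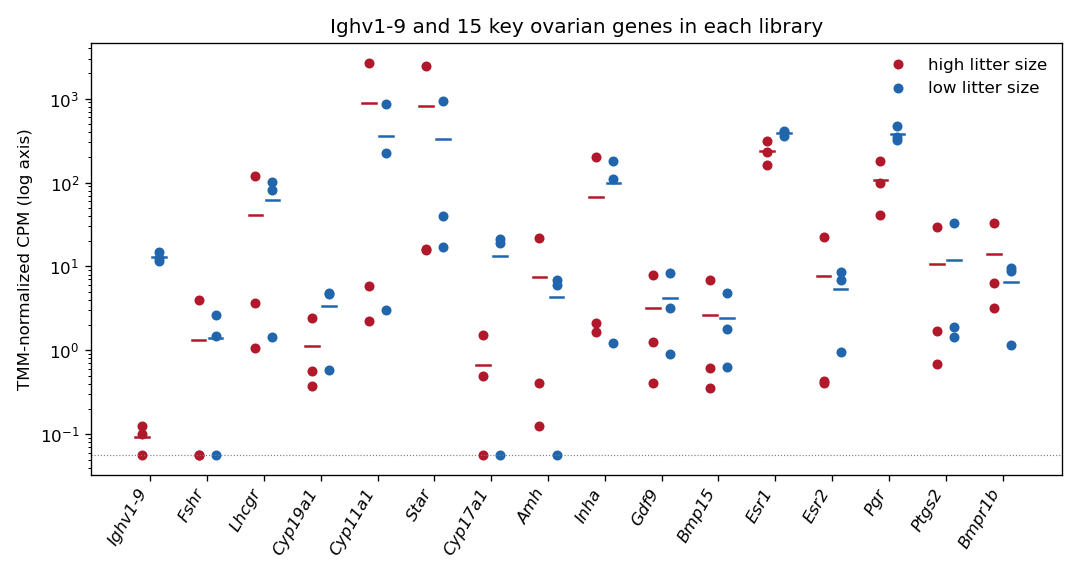
TMM-normalized CPM (log axis) of Ighv1-9 and the 15 key ovarian genes in each library, with high litter size in red, low litter size in blue, points for libraries and bars for group means (n = 3). Values under 0.0568 CPM, including 0, are drawn at the dotted line. Cyp11a1 ranged from 2.25 to 2681 CPM within the high group and from 3.04 to 856 CPM within the low group.

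The other genes of smallest p in each direction did not pass the test with edgeR, and the following are values. Among genes with higher values in the high group, Trp63, a transcription factor of stratified epithelium (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102), had 11.8 ± 2.66 CPM against 0.862 ± 0.344 CPM (SD, n = 3; log2 fold change 3.76, adjusted p = 0.14). Fat2, an atypical cadherin (chromosome 11, 55250609 to 55336564), had a log2 fold change of 5.72. Krt15, a keratin of basal epithelial cells (chromosome 11, 100131758 to 100135928), had 5.94. Cnr1, the cannabinoid receptor (chromosome 4, 33924593 to 33948831), had 4.43, and Cish, an inhibitor of cytokine signalling (chromosome 9, 107296026 to 107302784), had 1.32. Among genes with lower values, Asic2, an acid-sensing ion channel (chromosome 11, 80880169 to 81968457), had 14.0 ± 3.12 CPM against 67.1 ± 4.17 CPM (SD, n = 3; log2 fold change -2.26, adjusted p = 0.14). Ptpn5, a protein tyrosine phosphatase (chromosome 7, 47077795 to 47133684), had a log2 fold change of -3.74, and it passed with DESeq2 (adjusted p = 2.3e-18), limma voom (0.0416) and scaling by library size alone (0.0268), and with edgeR without high replicate 3 (0.0253). Slc39a2, a zinc transporter (chromosome 14, 51892889 to 51896745), had -4.43. Ighv1-15, another heavy chain variable segment (chromosome 12, 114657353 to 114657786), had -4.57.

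None of the 15 key ovarian genes passed. Star, which moves cholesterol into mitochondria, had 15.8, 16.2 and 2418 CPM in high replicates 1, 3 and 4 and 39.6, 16.8 and 932 CPM in low replicates 1, 2 and 5 (log2 fold change 1.31, SE 2.17, adjusted p = 0.819). Cyp11a1, which makes pregnenolone from cholesterol, had a log2 fold change of 1.31 (SE 2.48, adjusted p = 0.843), and the value was -6.54 without high replicate 4. Inha, the inhibin alpha subunit of granulosa cells, had 1.64, 2.12 and 199 CPM in the high libraries and 182, 1.23 and 110 CPM in the low libraries. The oocyte growth factors Gdf9 and Bmp15 had log2 fold changes of -0.39 (SE 1.17) and 0.10 (SE 1.22). The gonadotropin receptors Fshr and Lhcgr had -0.07 (SE 1.87) and -0.57 (SE 1.80), and Amh had 0.80 (SE 1.96). The steroid enzymes Cyp19a1 and Cyp17a1 had -1.58 (SE 0.99) and -4.30 (SE 1.96, adjusted p = 0.381), and without high replicate 4 Fshr had -7.79, Lhcgr -4.76, Amh -3.98 and Cyp19a1 -2.85. Pgr, the progesterone receptor, had 107 ± 70.5 CPM in the high and 383 ± 83.1 CPM in the low group (SD, n = 3; log2 fold change -1.84, adjusted p = 0.24 with edgeR and 0.016 with DESeq2). Esr1, the oestrogen receptor alpha, had -0.74 (SE 0.30, adjusted p = 0.336), and Esr2 had 0.52 (SE 1.55). Ptgs2 had -0.16 (SE 1.64), and Bmpr1b, a BMP receptor linked to litter size in sheep, had 1.11 (SE 1.05).

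None of the 29 gene lists held a member that passed over all genes tested, since Ighv1-9 is in no list. The lists of ovarian cell types did not pass by camera without a covariate and with all 6 libraries. Steroidogenesis genes (18 tested, 16 with positive and 2 with negative log2 fold changes) had an adjusted p of 0.92, luteal cell markers (11 tested) 0.777, oocyte markers (18 tested) 0.417, granulosa cell markers (17 tested) 0.168 and theca cell markers (11 tested) 0.65. Adjusted over the list alone, 1 granulosa marker passed, Inhbb, an inhibin beta subunit, with 78.6 ± 43.4 CPM in the high and 687 ± 179 CPM in the low group (SD, n = 3; log2 fold change -3.13, adjusted p over all genes 0.14). Inhbb did not follow the granulosa gene Inha between libraries. In low replicate 2 Inhbb had 629 and Inha 1.23 CPM, and in high replicate 4 they had 128 and 199 CPM. Inhba had -1.87, the HDL receptor Scarb1 2.03, the prostaglandin F receptor Ptgfr 1.83, the oocyte genes Tle6 and Ddx4 0.62 and -0.83, and the hedgehog receptor Ptch1 1.30. The median of oocyte markers, as log2 CPM centred per gene, spanned 3.61 within the high group and 3.40 within the low group. Oviduct and ciliated epithelium markers spanned 5.11 within the high group. The log2 fold changes of granulosa markers had a median of 0.15 and a mean of -0.13. Granulosa markers passed as lower without high replicate 4 (adjusted p = 0.000404) and without low replicate 2 (0.000626), and oocyte markers likewise (0.000296 and 0.00429). With the adipocyte marker level as a covariate, added after the data were seen, granulosa markers passed as higher (mean log2 fold change 2.17, adjusted p = 0.0487). Without high replicate 4, Inhba had -3.89, Scarb1 0.86, Ptgfr -1.23, Tle6 -0.42 and Ddx4 -1.63, and without high replicate 3 Ddx4 had -0.30.

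**Figure D2:**
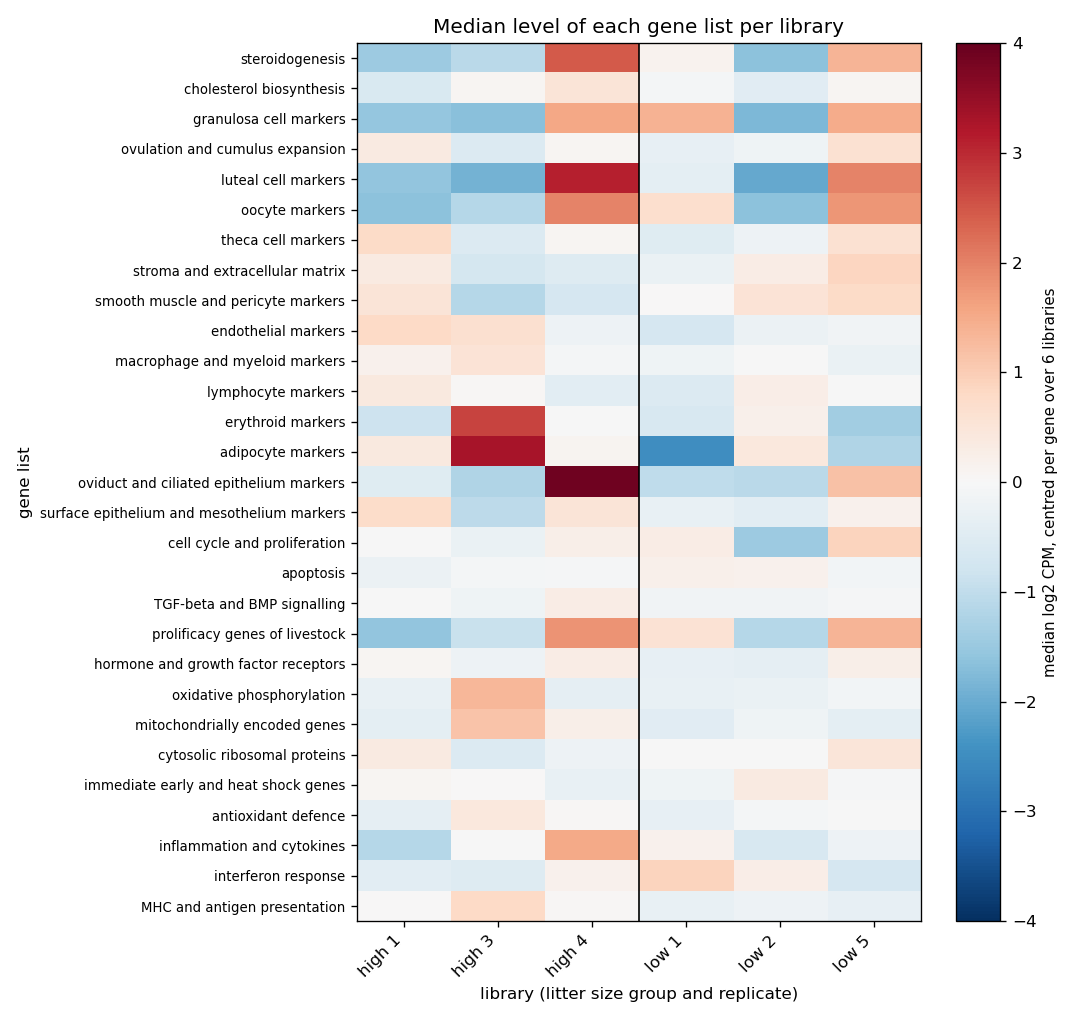
Median log2 CPM of each of the 29 gene lists (rows) in each library (columns), centred per gene over the 6 libraries, with red above and blue below the mean. Oocyte markers span 3.61 within the high and 3.40 within the low group.

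Adipocyte markers were higher in the high group as a list (13 of 13 tested members with positive log2 fold changes, camera adjusted p = 0.000105, adjusted p = 0.953 with an estimated correlation). Pparg, the regulator of fat cell differentiation, had a log2 fold change of 2.27 and Cidea, a lipid droplet protein, 4.08, and in none of the 8 lists that passed by camera did a member pass adjusted over the list alone (0 of each). The list's median was 0.377, 3.30 and 0.105 in high replicates 1, 3 and 4 and -2.48, 0.433 and -1.19 in low replicates 1, 2 and 5. Low replicate 2 thus lay above high replicates 1 and 4. Without high replicate 3 the list's mean log2 fold change went from 2.57 to 0.92 (adjusted p = 0.0135), Pparg to 1.44 and Cidea to 1.91. Endothelial markers were higher (15 of 15 positive, adjusted p = 0.00011, adjusted p = 0.953 with an estimated correlation), with Esam at 1.12 and the endothelial cadherin Cdh5 at 1.13. Antigen presentation genes were higher (20 of 21 positive, adjusted p = 0.000269, adjusted p = 0.953 with an estimated correlation). Without high replicate 3 their mean log2 fold change went from 0.67 to 0.31 (camera adjusted p = 0.0845 with the preset correlation). The invariant chain Cd74 had 1.08 and its regulator Ciita 0.83. With the adipocyte covariate, the mean log2 fold change of endothelial markers went from 0.80 to 0.40 (adjusted p = 0.093) and that of antigen presentation genes from 0.67 to 0.17 (0.225).

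Mitochondrially encoded genes were higher (13 of 13 positive, camera adjusted p = 0.0039, adjusted p = 0.953 with an estimated correlation), with mt-Nd4l at 1.36 and mt-Atp8 at 1.23. Oxidative phosphorylation genes were higher (29 of 29 positive, adjusted p = 0.018, adjusted p = 0.953 with an estimated correlation), with Sdhc at 1.40 and Uqcrfs1 at 1.18. Neither list passed without high replicate 3 (adjusted p = 0.196 and 0.294), and the mean log2 fold change of oxidative phosphorylation genes was then -0.10. Without high replicate 3, mt-Nd4l had 0.74, mt-Atp8 0.61, Sdhc 0.21 and Uqcrfs1 0.081, and the mean of mitochondrially encoded genes was 0.27. Without low replicate 1 the oxidative phosphorylation genes had an adjusted p of 0.0644 and a mean of 0.60, against 0.66 with all libraries. With the adipocyte covariate, the mean of mitochondrially encoded genes went from 0.84 to 0.028 (adjusted p = 0.986) and that of oxidative phosphorylation genes to -0.38 (0.0695). The medians of both lists and of the adipocyte markers were highest in high replicate 3. Mitochondrial mRNA made up 3.67, 8.39 and 5.65% of counts in the high libraries and 3.22, 4.10 and 3.48% in the low libraries (exact two-sided permutation p = 0.2, where 0.1 is the smallest possible).

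Smooth muscle and pericyte markers were lower (11 of 13 negative, camera adjusted p = 0.0168, adjusted p = 0.953 with an estimated correlation), with the smooth muscle actin Actg2 at -1.90 and the pericyte receptor Notch3 at 1.20. Stroma and extracellular matrix genes were lower (14 of 18 negative, adjusted p = 0.0324, adjusted p = 0.953 with an estimated correlation), with the collagen Col6a3 at -1.85 and Ogn at -1.51. Ribosomal protein genes were lower (32 of 35 negative, adjusted p = 0.018, adjusted p = 0.953 with an estimated correlation), with Rps18 at -0.97 and Rpl5 at -0.49. Ribosomal protein genes have many processed pseudogenes, so these values are uncertain. These 3 lists lost their calls without high replicate 3, high replicate 4 or low replicate 5, with adjusted p from 0.106 to 0.552. In these 3 fits the mean log2 fold change was -0.36, -0.49 and -0.46 for smooth muscle, -0.40, -0.44 and -0.21 for stroma and -0.055, -0.17 and -0.040 for ribosomal proteins. Without high replicate 1 the means were -1.13, -0.99 and -0.51, and Rpl5 had -0.29 without high replicate 3. Without low replicate 2 the mean of ribosomal proteins was -0.12. They also lost them with the adipocyte covariate, where the mean log2 fold change of smooth muscle markers went from -0.61 to -0.43 (adjusted p = 0.152), that of stroma genes from -0.56 to -0.45 (0.1) and that of ribosomal protein genes from -0.22 to 0.031 (0.983).

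The surface epithelium and mesothelium list moved in both directions, with a camera adjusted p of 0.838. Adjusted over the list alone, 4 members were higher and 5 lower, and over all genes 0 passed. Krt8, a keratin of simple epithelium, had 125 ± 46.4 CPM in the high and 693 ± 373 CPM in the low group (SD, n = 3; log2 fold change -2.47), and the epithelial cadherin Cdh1 had -1.84. The oviduct list (11 tested, adjusted p = 0.37) held Pax8 at -1.20 and Deup1 at 1.85, which was 1.07 without high replicate 4.

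The remaining lists did not pass by camera. Adjusted over the list alone, members passed as follows, with 0 over all genes. Among immediate early genes (21 tested, camera adjusted p = 0.528) 1 was higher and 3 were lower, with Klf4 at -1.90 and Junb at -0.95. Among inflammation genes (19 tested, 0.733) 2 were higher and 2 lower, with the NF-kappa-B inhibitor Nfkbia at -0.99 and the chemokine Ccl7 at -2.03. In the ovulation list (15 tested, 0.913) 1 was higher, the prostaglandin receptor Ptger2, at 1.87, and the protease Adamts4 had -1.55, or -0.98 without low replicate 5. Among TGF-beta and BMP genes (27 tested, 0.168) 1 was higher, Id3, at 1.26, and Acvr1b had -1.44. Among hormone and growth factor receptors (20 tested, 0.417) 1 was lower, the oxytocin receptor Oxtr, at -1.91, and Kitl had 0.78. Among interferon genes (21 tested, 0.1) 1 was lower, Bst2, at -1.22, and Oas1a had -1.47, or -0.97 without low replicate 1. Cholesterol biosynthesis genes (22 tested, 0.429) held Hmgcs1 at 2.23.

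No member passed adjusted over the list alone in the following 7 lists. Antioxidant genes (23 tested, camera adjusted p = 0.733) held Gpx1 at -1.29 and Gstm1 at 1.05. Apoptosis genes (21 tested, 0.168) held Bak1 at -0.76. Cell cycle genes (23 tested, 0.975) held Ccnd2 at 2.30, or 0.98 without high replicate 3, and Mcm2 at -0.34, or -0.054 without low replicate 5. Macrophage markers (17 tested, 0.1) held Mpeg1 at 1.11 and Itgam at -1.85. Lymphocyte markers (17 tested, 0.733) held Ighm at 1.59 and Trac at 1.43, which were 0.64 and 0.85 without high replicate 3. Erythroid markers (7 tested, 0.168) held Hba-a2 at 5.87 and Alas2 at 2.52. Hba-a2 had 203 CPM in high replicate 3 and 8.23 and 4.52 CPM in high replicates 1 and 4. Without high replicate 3 it had 2.37, Alas2 0.65, and the list's mean went from 1.88 to 0.068. Without low replicate 2, Hba-a2 had 13.50, a fitted value with counts in no remaining low library. Prolificacy genes of livestock (17 tested, 0.417) held Esr1, given above, and Rbp4 at 2.08, or 0.84 without high replicate 3.

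Some of these lists passed by camera with 1 library left out. Cell cycle genes were lower without low replicate 2 (adjusted p = 0.00037) and higher without low replicate 5 (0.0454). Interferon genes were lower without low replicate 5 (0.000282) and without high replicate 4 (0.018). Macrophage markers were higher without high replicate 4 (0.019) and without low replicate 2 (0.0342). Erythroid markers were higher without high replicate 1 (0.0201) and without low replicate 2 (0.0342). Cholesterol biosynthesis genes were higher without high replicate 1 (0.0129), apoptosis genes lower without low replicate 5 (0.0432) and prolificacy genes lower without low replicate 2 (0.0331).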

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

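Covariates and the joint removal of libraries were chosen after the data were seen, and so was the choice of libraries removed, which were those of lowest ovarian markers. That removal leaves high replicate 4 alone against low replicates 1 and 5, so its values describe this 1 library, which is assumed to vary like the low group, and say nothing on the stability of the comparison. No paired analysis was possible because the groups share only 1 replicate number. For genes called, the main count was 1 (0 higher, 1 lower). DESeq2 gave 1026 (354 higher, 672 lower), the edgeR likelihood ratio test 631 (157 higher, 474 lower), limma voom 3 lower and library size alone 2 lower, and Ighv1-9 was among the calls of each. RLE, upper-quartile scaling, both filters, robust dispersion and both thresholds gave 1. With DESeq2 calling 43 genes in simulated data with no change, part of its count is open to false calls. The simulation drew each gene independently, so 43 does not bound that part. Other splits of the real libraries into 3 and 3 gave DESeq2 up to 224 genes. Leaving out 1 library gave 0 to 1 genes. The count was 0 without high replicate 1, high replicate 4 or any of low replicates 1, 2 and 5, and without high replicate 3 the 1 gene was Ptpn5, not Ighv1-9. It was 0 with the granulosa and oocyte marker covariate, 0 with the adipocyte covariate and 0 with high replicates 1 and 3 and low replicate 2 left out, which leaves 1 high library, with 2070, 1193 and 1742 genes at an unadjusted p under 0.05. Fewer libraries or residual degrees of freedom enter these fits; the cause was not tested further.

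For gene lists, the main count was 8, and RLE, the 1 CPM filter, ranks and the granulosa and oocyte covariate gave 8, though oxidative phosphorylation genes lost their call with that covariate (adjusted p = 0.0796) and oviduct markers gained one (0.0117). An estimated correlation and fry gave 0 and 0. Leaving out 1 library gave 2 to 14 lists, 2 without high replicate 3 and 14 without low replicate 2. The adipocyte covariate gave 3, which were granulosa markers, oviduct markers and cell cycle genes, and the 8 main calls were lost. That of the adipocyte list was lost by construction, since its own level was the covariate. The covariate was 0.33, 3.13 and 0.12 in the high and -2.62, 0.37 and -1.32 in the low libraries, so it partly followed the grouping. The loss of the other calls therefore cannot separate fat content from the group difference. The cause was not tested. Of the 80 named genes, 13 changed sign when some library was left out and 4 under DESeq2, voom, RLE or library size, and 41 passed under DESeq2. Of the 29 lists, 15 changed the sign of their mean when some library was left out. The depth, at 0.0568 CPM for 1 count in the smallest library before TMM normalization, limits statements on genes under about 1 CPM.

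Ranges of mean log2 fold changes over the 6 fits with 1 library left out, for lists that changed sign, were steroidogenesis -2.52 to 1.32, granulosa cell markers -2.73 to 0.30, ovulation and cumulus expansion -0.33 to 0.61, luteal cell markers -2.84 to 2.09, oocyte markers -2.70 to 1.08. Others were theca cell markers -0.45 to 0.38, lymphocyte markers -0.056 to 0.34, oviduct and ciliated epithelium markers -0.96 to 2.98, surface epithelium and mesothelium markers -0.29 to 0.17, cell cycle and proliferation -0.45 to 0.34. Others were prolificacy genes of livestock -2.20 to 0.32, hormone and growth factor receptors -0.86 to 0.72, oxidative phosphorylation -0.10 to 0.89, immediate early and heat shock genes -0.23 to 0.058, inflammation and cytokines -0.50 to 1.64. For named genes they were Fshr -7.79 to 0.77, Lhcgr -4.76 to 0.019, Cyp11a1 -6.54 to 2.97, Star -4.41 to 4.85, Amh -3.98 to 1.38. Others were Inha -5.73 to 0.27, Gdf9 -2.38 to 0.62, Bmp15 -2.35 to 1.11, Esr2 -3.70 to 1.10, Ptgs2 -3.34 to 2.67. Others were Bmpr1b -0.51 to 1.59, Ptgfr -1.23 to 4.56, Tle6 -0.42 to 0.96. With voom, log2 fold changes of opposite sign were Cyp11a1 -1.24, Bmp15 -0.63, Esr2 -1.18. With library size alone it was Fshr 0.033. With the granulosa and oocyte covariate, means of opposite sign were ovulation and cumulus expansion -0.017, theca cell markers 0.032, lymphocyte markers -0.00052, cell cycle and proliferation 0.23. With the adipocyte covariate they were granulosa cell markers 2.17, theca cell markers 0.36, macrophage and myeloid markers -0.081, lymphocyte markers -0.25, erythroid markers -0.42. Others were adipocyte markers -0.013, cell cycle and proliferation 0.50, prolificacy genes of livestock 1.33, oxidative phosphorylation -0.38, cytosolic ribosomal proteins 0.031. Others were antioxidant defence -0.15. With 3 libraries left out, so that high replicate 4 stood alone against low replicates 1 and 5, they were granulosa cell markers 0.46, lymphocyte markers -0.39, prolificacy genes of livestock 0.14, oxidative phosphorylation -0.20. The cause was not tested.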

Other observations

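All tests in this part except those on plasma cells, shared reads and the heavy chain haplotype were chosen after the results were seen, as were the gene lists. The requirement that a verdict hold with each library left out was also added after the values were seen.

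Of a list of stratified epithelium genes, drawn up after Trp63 and Krt15 were seen, 9 of 11 tested members had positive log2 fold changes, with a median of 3.48 (2.43 to 3.91 with each library left out) and 0 members past the edgeR threshold (5 by DESeq2). Of the 7 at an unadjusted p under 0.05, Sfn (-2.13) and Perp (-1.54) were negative, and Trp63 and Krt15 had prompted the list. Krt5, a keratin of basal cells, had 81.5, 68.2 and 207 CPM in high replicates 1, 3 and 4 and 2.89, 12.9 and 0.43 CPM in low replicates 1, 2 and 5. The members did not move together: in high replicate 3, Krt14 had 1.62, Krt13 0.69, Dsg3 0.87 and both Krt6a and Dsc3 0 CPM. Prss29, an implantation serine proteinase of uterine glands, had 330 CPM in high replicate 1 and at most 3.02 CPM in the other libraries.

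Ovarian marker genes differed widely between libraries of one group. The summed CPM of 10 oocyte-restricted genes was 2.05, 4.74 and 103 in high replicates 1, 3 and 4 and 22.4, 3.31 and 74.4 in low replicates 1, 2 and 5, so the highest exceeded the lowest 22.5 times in the low and 50.2 times in the high group. Effective library sizes differed by at most 1.48 times, which argues against depth and scaling. A differing share of ovarian tissue in the samples may account for the spread, and the Mullerian tract gene Hoxa10 was present at 29.8 to 293 CPM in every library. All 10 genes are members of the fixed oocyte list, so this is not independent of it. The labels give litter size only as high or low, and no biological explanation was tested.

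Oestrogen-induced uterine genes had lower values in the high group, with 10 of 11 tested members negative, a median log2 fold change of -2.26 (-3.44 without high replicate 4) and 0 past the edgeR threshold (5 by DESeq2). Ltf had 89.1, 813 and 3684 CPM in the high and 14150, 4676 and 3186 CPM in the low libraries. General epithelial genes had a median of -1.72, from -2.35 to -1.42 with each library left out, so a smaller share of simple epithelium may account for part of it, although 4 of its 12 members are also in the surface epithelium list, seen before. The Hox genes had a median of 0.657, which became -1.35 without high replicate 1, and the progesterone-induced genes 2.31, which became 0.807 without it, so the share of uterine tissue and the cycle stage stay open. Litter size itself stays open and untested.

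Heavy chain variable segments had lower values in the high group, with 24 lower and 0 higher of 60 at an unadjusted p under 0.05. Plasma cell genes had a median log2 fold change of -0.464 (-1.07 without high replicate 1), against -3.52 for those 24, which were picked for low values, and -2.12 for all 60. The gap exceeded the SD of the plasma cell genes (1.05), which met the bound set in advance against a lower plasma cell content. Because the 24 were picked for low values, which widens the gap, that bound cannot decide the question. A lower plasma cell content stays open, since 10 of the 13 plasma cell genes were negative, Igha with -1.44, Jchain with -1.05 and Iglc2 with -2.69. Of the positive ones, Ighm had 1.59. The summed level was 123, 62.8 and 24.4 CPM in the high and 270, 242 and 296 CPM in the low libraries, a log2 ratio of -1.94. Of the 60 segments, 11 had positive log2 fold changes, 0 of them at an unadjusted p under 0.05, and 49 had negative ones. The bound set in advance against reads shared between paralogs, a log2 difference over 1 for every pair of libraries, was missed by 1 pair. That pair was high replicate 1 with 123 and low replicate 2 with 242 CPM, so shared reads could not be decided by that bound. Shared reads were to give a summed log2 difference under 1, as also set in advance. They were also to give segments both higher and lower at an unadjusted p under 0.05. With -1.94, and 0 higher against 24 lower, neither was seen. These values argue against sharing among the 60 segments as the whole cause. 6 segments were under 0.5 CPM in all high and at least 1 CPM in all low libraries, and 0 the other way round, so another heavy chain haplotype could not be decided. Litter size stays open and untested.

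The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. 3 of the 10 gave at least the 1 gene of the real split with edgeR, and the highest other split gave 1. DESeq2 gave 1026 genes in the real split and at most 224 in the others, so 1 of 10 reached it. For gene lists, 9 of 10 splits gave at least the 8 of the real one, and the highest other split gave 20. No test addressed the cause, and the count for the real split was 0 with an estimated correlation.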
